A study of Hordeum vulgare with 24 samples.

How the data were processed

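Small RNA was sequenced from 24 shoot samples of barley seedlings grown in hydroponics, 3 for each of 8 combinations of cultivar, potassium (K) supply and day of treatment. Per the labels' protocols, libraries were made with the TruSeq small RNA kit, sequenced on a HiSeq 2500 and filtered with the ACGT101-miR program, which removed adapter dimers, junk and low-complexity reads, common RNA families and repeats. The protocol text speaks of a smaller number of libraries than the samples it is attached to, and the 24 samples were taken as separate libraries. Per the file headers, reads were then mapped to miRBase precursors, the genome and expressed sequences, and the raw value of an entry was taken from the reads of all isoforms at one end of the precursor. The genome build is not given in the sources used here, so positions are printed only as the deposited table gives them.

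The deposited raw values are expected counts, because the authors' program left fractions in 53 of the 1077 entries with values. The deposited normalized values are a signal: in each library they equal the raw count times 1 constant, with a largest relative spread of 9.33e-15, and how the authors found the constants is not given in the sources used here. Another 11 lines of the table held no values and were not used. Because 113 entries repeated the counts of another entry exactly, as happens when 1 mature sequence is assigned to several precursors, entries with identical counts in all libraries were kept once. This left 964 distinct profiles, 62 of them standing for 2 or more entries. A profile keeps the authors' name, in which L and R give bases added or removed at the ends, ss gives substitutions against the miRBase sequence, p5 and p3 mark an arm without its own miRBase entry, and PC marks a candidate predicted by the authors' program. Of the 964 profiles, 84 were identical to a miRBase sequence, 267 differed from it and 613 were not listed there. Near-identical members of a family can share reads, so counts were also summed over each of 173 families, with the number in the name taken as the family and all predicted candidates left out of the sums.

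The table lists essentially no low values: in profiles without fractions, 2 of the 9734 listed values lay between 1 and 4, and 55.5% of all values were exactly 0. A value of 0 can therefore mean a level under the authors' minimum, and such a profile is described as listed at 0, with no fold and no upper limit. Counting intervals were not computed, since sequencing reads without molecular identifiers are not independent molecules.

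Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test (robust option off) with TMM factors, the filterByExpr filter by group (minimum count 10, minimum total count 15) and Benjamini-Hochberg adjustment, with a call at an adjusted p under 0.05. All 24 libraries entered 1 model with a coefficient per group. This kept 480 profiles and 92 families. Levels are given as CPM, the count divided by the TMM-scaled total and multiplied by 1e+06, as mean ± SD. TMM factors were found separately for profiles and for family sums, so CPM of a profile and of its family are not on 1 scale. The 13 comparisons were low K against control in each cultivar on each day and on average, XZ153 against ZD9 under control K on each day, 7 days against 2 days under control K in each cultivar, and the differences of the low K response between cultivars and between days. Standard errors were taken from the F statistic and the log2 fold change.

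Family lists were fixed by family number and tested with fry of limma 3.58.1 on log2 CPM with a prior count of 1, adjusted over all 13 lists and 13 comparisons. The fry p tests whether the profiles of a list moved, on balance, one way, and does not compare the list with other profiles. The lists were the phosphate starvation, copper-related, sulfate, nitrogen-related, auxin signalling, phase change, leaf growth and shape, small RNA machinery, calcium and stress signalling, resistance gene, reproductive tissue and wheat and barley families, and the predicted candidates. The reproductive tissue list (miR2118 and miR2275) served as markers of tissue that a seedling shoot should lack, and miR2118 also stands in the resistance gene list.

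Groups, tests, lists, alternatives and the rule for named profiles were set before the data were examined. The rule names, per comparison, the 10 passing profiles with the largest positive and the 10 with the largest negative log2 fold change, with a mean CPM of at least 10 and no overlap between replicates. Where fewer than 5 passed, it names the 5 profiles with the smallest unadjusted p and a mean CPM of at least 10. It adds up to 4 families per list with the smallest p, 19 families whatever their values, and the 5 profiles with the most counts.

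Shares of length classes were compared by permutation of K labels within cultivar and day, two-sided, with 100000 resamples. The agreement of responses was measured as a correlation across profiles, against all 400 reassignments of K labels. The number of profiles and families without overlap was also counted over all 10 splits of the compared libraries, chosen after seeing the data, since tied zeros lower the chance share. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

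The tests were tried on simulated counts drawn from the means and library sizes of the real profiles. Each profile was drawn independently, around a mean shared by all libraries apart from the set changes. Shifts of whole libraries, as between real replicates, were not simulated, so the recovery and false calls that follow hold only for such counts. Among 480 simulated profiles with 200 changed, the comparison of low K with control in ZD9 at 2 days recovered 1.49% of those changed 4-fold, 19.4% of those changed 16-fold and 51.5% of those changed 64-fold. For XZ153 against ZD9 at 2 days the shares were 1.49%, 17.9% and 50.0%. For the mean low K comparison they were 40.3%, 91.0% and 97.0%, with 10 false calls among 264 unchanged profiles. Among 92 simulated families, the mean low K comparison recovered 60.0% at 4-fold and 93.3% at 16-fold, and the comparison of XZ153 with ZD9 at 2 days recovered 26.7% and 66.7%. Among 10 simulated lists of 20 profiles, the list shifted 8-fold had an adjusted p of 5.39e-07 by fry, and 0 of the unshifted lists passed.

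The alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, a mean CPM of at least 10, a fit to the compared libraries alone, the replicate number as a block, limma on log2 of the authors' normalized values plus 1, camera with an estimated correlation, family sums as list members, and leaving out each library. Chosen after seeing the data were fits without 3 families that differ most between replicates (miR5368, miR6173 and miR4995), with their log2 share as a covariate, without the library with the fewest counts, and without both. Each of the 24 libraries was used in the main tests. Replicates of the same group were compared by a chi-square test of their counts, and the lowest value was 15.2 per degree of freedom over 24 pairs. No library was therefore taken as a second deposit of another replicate of its group. Libraries of different groups were not compared in this way. The labels do not say whether replicates came from separate pots or pools, so p-values measure only the spread between these samples, which may be technical.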

Results

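MicroRNAs (miRNAs) are short RNAs, mostly of 20 to 24 nt, that direct the cleavage or block the translation of matching messenger RNAs. They were counted by small RNA sequencing in shoots of barley (Hordeum vulgare) seedlings of 2 genotypes, ZD9, labelled as sensitive to low potassium (K), and XZ153, a Tibetan wild barley labelled as tolerant. Seedlings grew in hydroponic solution with 1 mM K (control) or 0.01 mM K (low K) and were sampled after 2 or 7 days, with 3 libraries in each of the 8 groups. The question behind the design is which shoot miRNAs respond to K shortage, and whether the tolerant and the sensitive genotype differ in them.

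The total over distinct profiles lay between 123457 and 531215 counts in 23 libraries, with 385 to 551 profiles above 0. The remaining library, ZD9 low K 7 days replicate 1, held 11851 counts and 185 profiles. When the other replicates of its group were thinned to the same total, with a minimum count of 5, they kept 194 and 181 profiles and shared 154 of these with each other, but 64 and 59 with that library. It thus differed from its replicates in which miRNAs it listed, beyond its depth. Values of ZD9 low K at 7 days rest in part on this library. Across 480 tested profiles, 434 were at 0 in at least 1 library, and the Spearman correlation between replicates ranged from 0.146 to 0.940. For ZD9 low K 7 days replicate 1 it was 0.431 and 0.403 with the other replicates. Other libraries also stood apart: XZ153 control 2 days replicate 2 (0.146 and 0.214) and XZ153 control 7 days replicate 3 (0.159 and 0.249). So did ZD9 control 2 days replicate 2 (0.368 and 0.379) and XZ153 low K 2 days replicate 3 (0.448 and 0.462).

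The single profiles with the most counts belonged to plant families known to control development and nutrient signalling, though as family sums miR5368 and miR6173 were higher. The profile osa-miR444b.1, a grass-specific regulator of MADS-box genes, held 6.94% of all counts (0.169% to 13.5% across libraries) and is placed at 2H 583383324 to 583383475. Next came ata-miR156a-5p, which holds back the adult phase through SPL genes, at 6.11% (0.103% to 13.2%, 3H 59655967 to 59656088). The growth regulator osa-miR396e-5p, assigned to no chromosome, held 5.64% (1.34% to 13.2%), and hvu-miR166a, which limits HD-ZIP III genes, held 5.11% (1.88% to 24.8%, 5H 593550033 to 593550132). The auxin response regulator ata-miR167f-5p held 3.67% (0.471% to 6.08%, 6H 136921507 to 136921626). This order follows counts pooled over libraries of different depth. As a mean of the percentages per library, hvu-miR166a had 5.50%, osa-miR396e-5p 5.39% and ata-miR156a-5p 5.29%.

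A large and unstable share of the counts belonged to the families miR5368, miR6173 and miR4995, which hold 143 profiles named after soybean or rubber tree entries. Together they took 0.234% to 67.5% of a library, and 6 libraries were under 10%. The lowest shares were 0.234% in XZ153 control 2 days replicate 2 and 0.344% in XZ153 control 7 days replicate 3. Next came 0.721% in ZD9 control 2 days replicate 2 and 1.72% in XZ153 low K 2 days replicate 3. These libraries also correlated poorly with their replicates. In XZ153 control shoots at 2 days the mean share was 38.7% ± 33.6 (SD, n = 3), and the highest replicate was 268 times the lowest. XZ153 control shoots at 7 days had 44.0% ± 37.8, with a ratio of 195. By contrast, ZD9 control shoots at 7 days had 33.2% ± 8.72. Low K and control libraries differed by 0.56 on the log2 scale in this share (two-sided permutation test within cultivar and day, p = 0.619). These 3 variable families weigh on all other levels given as a share of counts, since they take up to 67.5% of a library. Replicates may be technical or biological, as the labels do not say which.

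**Figure D1:**
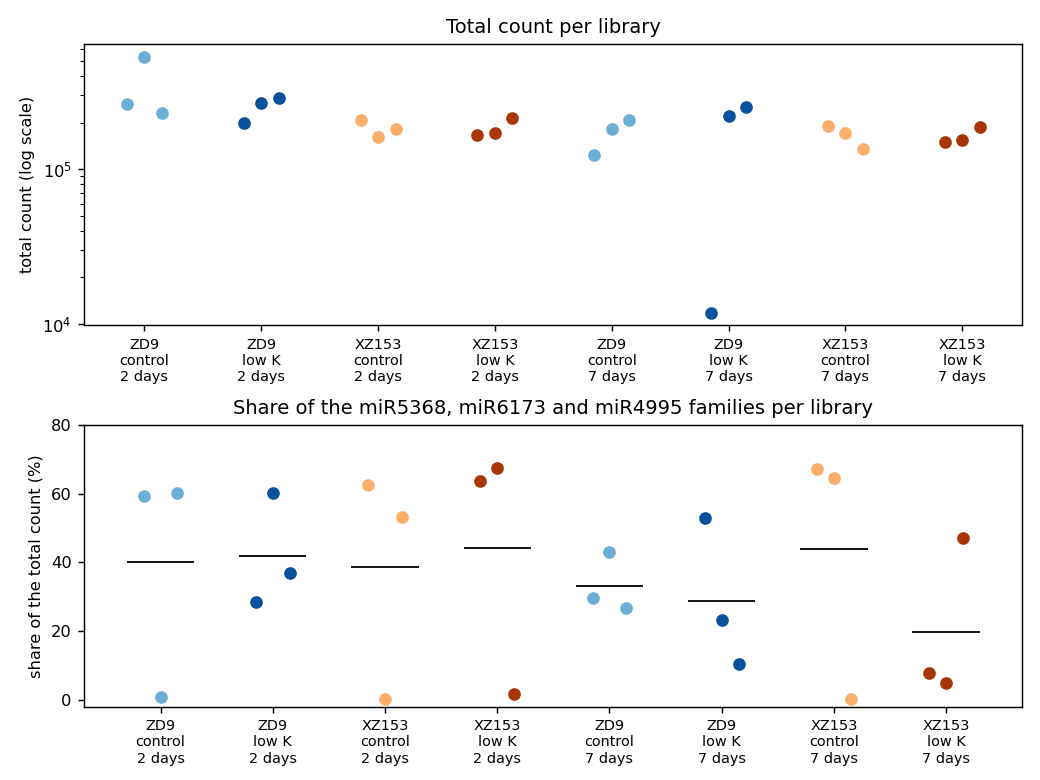
Total count per library on a log axis (top) and the share of counts in miR5368, miR6173 and miR4995 in percent (bottom), with 1 point per library by cultivar, K supply and day, and lines at group means of the share. The library ZD9 low K 7 days replicate 1 stands out with 11851 counts, and the share differs between replicates of most groups.

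Averaged over both genotypes and both days, low K left the conserved nutrient miRNAs of the shoot without a change that passed by edgeR. The sulfate starvation family miR395, which targets ATP sulfurylases and a sulfate transporter, had the lowest averaged log2 fold change among the 16 families without a group at 0, mainly from XZ153. The nitrogen-related family miR444, the growth regulator miR396 and the phase change family miR156 were abundant, with means close to control, and miR169 had a higher mean. The phosphate starvation signal miR399 was seen in few libraries.

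By edgeR, 0 of 480 profiles and 0 of 92 families passed for the mean low K response, with 24 profiles and 4 families at an unadjusted p under 0.05, where chance gives 24 and 4.6. DESeq2 called 8 profiles and 2 families. Family miR395 had 614 ± 471 CPM under low K and 1425 ± 1064 under control (SD, n = 12 each), a log2 fold change of -0.94 with a standard error (SE) of 0.52 and an adjusted p of 0.956 by edgeR. In XZ153 its log2 fold change was -1.63 at 2 days and -2.34 at 7 days, and in ZD9 -0.64 and 0.84, with an SE from 1.03 to 1.07, and none passed. For miR169, a regulator of NF-Y transcription factors, the values were 9384 ± 3695 and 6838 ± 2499 CPM, a log2 fold change of 0.41 with an SE of 0.28. Family miR396 had 68429 ± 16234 and 61534 ± 19654 CPM (0.19, SE 0.21), and miR156 had 59373 ± 25745 and 70096 ± 35217 CPM (-0.15). The laccase regulator miR397 stood at 3808 ± 7371 and 10711 ± 18292 CPM, a log2 fold change of -0.62. This average joins opposite signs, -1.50 and -2.64 in ZD9 and 0.80 and 0.86 in XZ153 at 2 and 7 days, with an SE from 1.04 to 1.10, and none passed. Family miR528 had 1073 ± 1656 and 2575 ± 3401 CPM, though the log2 fold change averaged over the 4 pairs of groups was 0.88 with an SE of 0.82. It too joins opposite signs, -1.37 and -1.71 in ZD9 and 2.36 and 4.25 in XZ153, with an SE from 1.62 to 1.90, and none passed. For miR827, which acts in phosphate transport, the values were 2511 ± 2915 and 1608 ± 731 CPM (0.51).

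The other families with a fold change were miR159 (-0.08), miR160 (-0.02), miR164 (-0.04), miR166 (-0.31), miR168 (-0.23), miR172 (-0.16), miR319 (-0.42), miR393 (-0.04) and miR444 (-0.09). Over the 16 families without a group at 0, 12 were negative and 4 positive, the SE ranged from 0.21 to 0.82, and the smallest unadjusted p was 0.0831 with an adjusted p of 0.956 by edgeR. Families miR398, miR399 and miR408 were listed at 0 in at least 1 group and have no fold. Their means under low K and control were 247 ± 598 and 1020 ± 1905 CPM for miR398, 2296 ± 7939 and 35.0 ± 58.3 CPM for miR399, and 2250 ± 4311 and 5964 ± 10367 CPM for miR408. The miR399 mean rests on the library with 11851 counts, where the family had 299 counts. Families miR319, miR393, miR396 and miR444 also had opposite signs in the 2 genotypes on both days, and none passed. For miR396 the values were -0.11 and -0.20 in ZD9 and 0.0075 and 1.07 in XZ153 at 2 and 7 days. The sign of miR156, miR160, miR164, miR172, miR319, miR393 and miR444 changed under at least 1 alternative. For miR156 and miR172 this was only with 1 library left out, and for miR444 only with libraries left out, with or without the variable families.

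**Figure D2:**
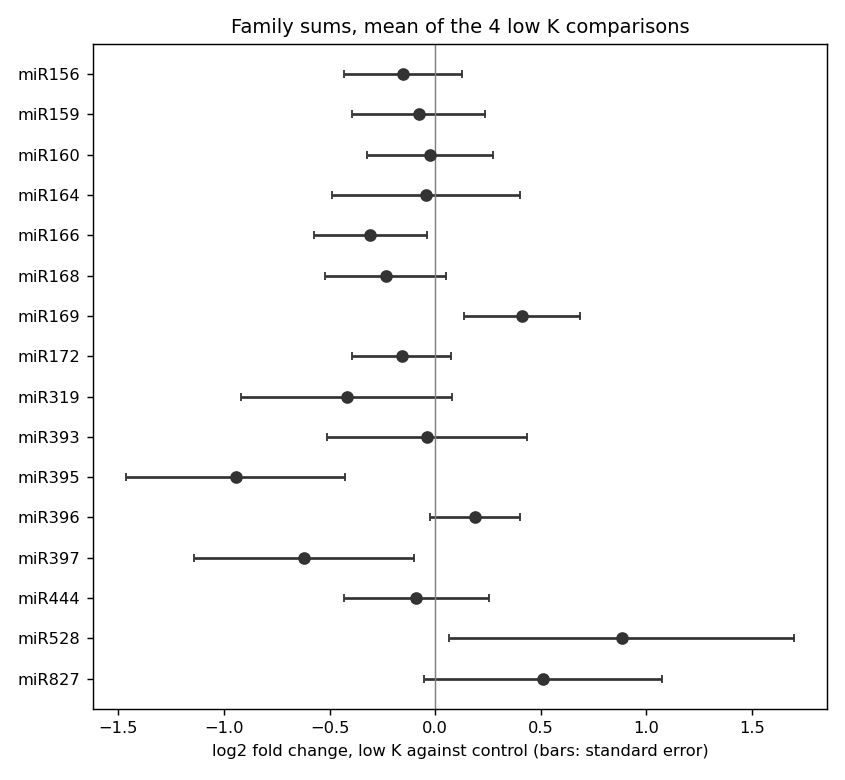
Mean log2 fold change of low K against control for 16 conserved miRNA families, averaged over both cultivars and both days, with points at the estimate and bars of 1 standard error. None of the 16 passed by edgeR, and miR395 has the lowest of these 16 estimates at -0.94.

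The 5 profiles with the smallest p in this comparison did not pass. Both miR395 profiles among them were seen mainly in control shoots: ata-miR395a-5p was above 0 in 9 of 12 control and 2 of 12 low K libraries (adjusted p = 0.289 by edgeR), and mtr-miR395h_L-1 likewise in 9 and 2 (adjusted p = 0.706 by edgeR). The other 3 were mtr-MIR2592aw-p5_2ss7TG17GT, in 10 control and 8 low K libraries, and gma-MIR4995-p5_2ss9GT20GC and hbr-MIR6173-p3_2ss9GT19GA, in 9 and 8 each (adjusted p = 0.706). The last 2 belong to the variable families, whose share differs between replicates. The profile mtr-MIR2592aw-p5_2ss7TG17GT lies outside these families but was also low where their share was lowest. Its counts in replicates 1 to 3 were 400, 20 and 230 in ZD9 control at 2 days. In XZ153 control at 7 days they were 309, 357 and 0.

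None of the 13 family lists passed in any of the 13 comparisons by fry of limma, and 0 passed by camera with an estimated correlation. The sulfate family had the smallest p for the mean low K response, with 7 of 7 profiles negative (p = 0.0151, adjusted p = 0.981 by fry; camera p = 0.00299 with an estimated correlation), and 2 of them were lower when adjusted over the list alone. The remaining 12 lists had 0 profiles passing when adjusted over the list alone. Copper-related families had 6 of 9 profiles negative and nitrogen-related families 21 of 27 positive. The phosphate starvation list, tested on profiles of 1 family only, had 2 of 2 positive. Auxin signalling families had 11 positive and 7 negative profiles, with a median of 0.20, a mean of -0.15 and a downward test. Phase change families, which time the juvenile to adult shift, had 14 positive and 13 negative, with a median and mean of 0.01 but a downward test. Unadjusted p by fry was 0.471 for copper-related, 0.674 for nitrogen-related, 0.901 for phosphate starvation, 0.868 for auxin signalling and 0.815 for phase change families, each with an adjusted p of 0.981.

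Leaf growth and shape families had 26 positive and 27 negative profiles. The small RNA machinery list was meant for families that target DCL1 and AGO genes. It was tested on profiles of 1 family only, with 0 positive and 2 negative. Calcium and stress signalling families had 3 positive and 1 negative, with a median of 0.39 and a mean of 0.22 but a downward test. Resistance gene families, which start phased small RNAs from NLR genes, had 5 positive and 4 negative, with a median of 0.00, a mean of -0.18 and a downward test. Wheat and barley families had 16 positive and 10 negative, the predicted candidates 24 and 15, and the reproductive tissue list 0 and 4. Of the reproductive families, miR2275 had 0 counts and miR2118, which also acts on resistance genes, had 6557 counts and was above 0 in 24 libraries. Unadjusted p by fry was 0.792 for leaf growth, 0.731 for small RNA machinery, 0.578 for calcium and stress, 0.762 for resistance gene, 0.754 for wheat and barley, 0.565 for predicted candidate and 0.602 for reproductive tissue profiles, each with an adjusted p of 0.981.

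In ZD9 shoots after 2 days of low K, the sensitive genotype showed no miRNA whose level passed as different from control by edgeR. The profiles with the smallest p were each seen in 1 or 2 libraries. A rare 5' arm of the sulfate miRNA miR395 was seen in control shoots alone.

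By edgeR, 0 profiles and 0 families passed, with 6 profiles and 0 families at an unadjusted p under 0.05; DESeq2 called 1 profile and 0 families. PC-5p-112605_131, ata-miR395a-5p and gma-MIR5368-p3_1ss3AG were listed at 0 in all 3 low K libraries and above 0 in 1, 1 and 2 control libraries. In turn, ptc-miR6478_R-1_1ss20TG and bdi-miR171c-5p, of a family that limits GRAS genes, were above 0 in 2 and 1 low K libraries and at 0 in control. None passed (unadjusted p from 0.0314 to 0.0479, adjusted p = 1 by edgeR). Replicates did not overlap for 6 of 480 profiles and 6 of 92 families, where chance gives 10% without ties. With the tied zeros of each comparison as they are, the mean over its 10 splits was 8.25% to 8.96% of profiles and 8.15% to 9.57% of families over the 8 comparisons of 2 groups. The median SE of a single comparison was 1.65, so a change had to be large to pass.

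In XZ153 shoots after 2 days of low K, the tolerant genotype also showed no miRNA that passed by edgeR. A precursor arm of miR169, the NF-Y regulator tied to nitrogen supply and drought, was seen in low K shoots and not in control. One miR390 profile, part of the auxin response pathway, was seen in a control library alone.

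By edgeR, 0 profiles and 0 families passed, with 10 profiles and 0 families at an unadjusted p under 0.05; DESeq2 called 1 profile and 0 families. The profile bdi-MIR169b-p5 had 93.7 ± 76.0 CPM in 3 low K libraries and was listed at 0 in 3 control libraries, yet did not pass (adjusted p = 1 by edgeR). Family miR395 had 818 ± 206 CPM under low K and 2541 ± 400 under control without overlap, and did not pass (adjusted p = 1 by edgeR). Profiles gma-MIR5368-p3_2ss17AC19AG and ptc-MIR156h-p5_2ss2AG17CA were above 0 in 2 of 3 low K libraries and at 0 in control. In contrast, ata-miR390-3p and hvu-miR5049c_L-2_1ss6AG were above 0 in 1 control library and at 0 under low K. No overlap between replicates was seen for 8 of 480 profiles and 6 of 92 families, where chance gives 10% without ties.

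In ZD9 shoots after 7 days of low K, the laccase regulator miR397 was lower than in control by its mean. A precursor arm of miR398 was at 0, but neither passed by edgeR. Both families respond to copper supply in plants. Higher levels of miR399, the phosphate starvation signal, came from 1 library.

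By edgeR, 0 profiles and 0 families passed, with 8 profiles and 5 families at an unadjusted p under 0.05; DESeq2 called 1 profile and 1 family. Family miR397 had 678 ± 643 CPM under low K and 4428 ± 4226 under control, a log2 fold change of -2.64 with an SE of 1.10 and an adjusted p of 0.599 by edgeR. The 2 groups overlapped, and its leading profile hvu-MIR397a-p5 was at 0 in the library with 11851 counts. Families miR399, miR437, miR1122 and miR5080 were the others at an unadjusted p under 0.05, and their low K means rest on the library with 11851 counts. That library had 4232 CPM of miR437, 1380 of miR1122 and 30265 of miR5080, while the other 2 replicates had 0 and 0, 0 and 11.4, and 367 and 237 CPM. The predicted candidate PC-3p-139466_63 was above 0 in 3 of 3 low K libraries, at 346 ± 554 CPM, and at 0 in control (adjusted p = 1 by edgeR). The library with 11851 counts gave 985 CPM of it from 25 counts, and the other replicates 20.5 and 32.3 CPM. Profiles ata-MIR398g-p5_2ss9GA21TC and PC-3p-40473_1290 were above 0 in 1 control library alone, and lus-miR159b_R+1 in 1 low K library alone. The profile gma-MIR5368-p5_1ss9AG had 25082 ± 42669 CPM under low K and 936 ± 461 under control, a log2 fold change of 4.74 with an SE of 2.03, but -0.87 without the library with 11851 counts. Replicates did not overlap for 96 of 480 profiles and 16 of 92 families, where chance gives 10% without ties and the highest other split gave 88 and 17.

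In XZ153 shoots after 7 days of low K, the growth regulator miR396 was above the control mean and the copper-related miR408 was seen under low K but not in control. Family miR6300, a short sequence first named in soybean, was also higher by its mean. None of these passed by edgeR, though this comparison held the most profiles at a small unadjusted p of the 4.

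By edgeR, 0 profiles and 0 families passed, with 43 profiles and 12 families at an unadjusted p under 0.05; DESeq2 called 10 profiles and 6 families. Family miR396 had 78038 ± 19196 CPM under low K and 37291 ± 16737 under control, a log2 fold change of 1.07 with an SE of 0.43. Family miR6300 had 9845 ± 7339 and 2720 ± 975 CPM, a log2 fold change of 1.86 with an SE of 0.61. For miR408, 55.7 ± 20.4 CPM under low K stood against a group listed at 0. Adjusted p of these families lay between 0.306 and 0.338 by edgeR. Family miR395 had 412 ± 432 CPM under low K and 2091 ± 615 under control (adjusted p = 0.338 by edgeR), and miR397 had 478 ± 79.4 and 262 ± 75.5 CPM, both without overlap and neither passed. The profile gma-miR6300_L-1R+8 had 844 ± 1228 CPM in 3 of 3 low K libraries and was at 0 in control (adjusted p = 0.176 by edgeR). In the other direction, mtr-MIR2592aw-p5_2ss7TG17GT had 1217 ± 1109 CPM in control, from 2 libraries, and was at 0 under low K. Profiles gma-MIR5368-p5_2ss9GT18TC, gma-MIR4995-p5_2ss9GT20GC and gra-MIR8723b-p3_2ss7AG18AG were above 0 in 1 control library each. For 41 of 480 profiles and 15 of 92 families replicates did not overlap, where chance gives 10% without ties. In this comparison the mean share of the 3 variable families was 44.0% ± 37.8 in control and 19.9% ± 23.6 under low K.

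Between genotypes under control K at 2 days, 2 copper-related miRNA families passed as different by edgeR. Families miR397 and miR398, which repress laccases and copper superoxide dismutases and save copper when it is short, were lower in XZ153 than in ZD9. Family miR319, which limits TCP genes in leaf growth, was higher in XZ153, and miR408 and miR528, of the same copper group, did not pass, nor did the copper-related list as a whole. A miR7757 precursor arm was found in XZ153 and not in ZD9.

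By edgeR, 2 of 480 profiles passed, 1 higher and 1 lower in XZ153, and 3 of 92 families, 1 higher and 2 lower. DESeq2 called 13 profiles and 6 families. Family miR397 had 447 ± 133 CPM in XZ153 and 37707 ± 18660 in ZD9, a log2 fold change of -6.40 with an SE of 1.31 and an adjusted p of 0.00821 by edgeR. Family miR398 was listed at 0 in XZ153 and had 3878 ± 1872 CPM in ZD9 (adjusted p = 0.0280 by edgeR). Family miR319 had 4956 ± 6912 CPM in XZ153 and 229 ± 35.2 in ZD9, a log2 fold change of 4.43 with an SE of 1.14 (adjusted p = 0.0288 by edgeR). It rested on XZ153 control 2 days replicate 2, without which the log2 fold change was 2.22 and the adjusted p 0.632, and it did not pass without any 1 ZD9 control library (0.149, 0.109 and 0.109 by edgeR). Family miR397 did not pass without XZ153 control 2 days replicate 1 or 2 (adjusted p = 0.0649 and 0.0811 by edgeR). Family miR398 did not pass without either of these (0.0649 and 0.0811) or ZD9 control 2 days replicate 1 (0.0553). Family miR528 had 46.7 ± 48.8 and 7528 ± 1224 CPM, and miR408 had 294 ± 388 and 20785 ± 11596 CPM, each with an adjusted p of 0.0517 by edgeR. The cereal family miR5051 had 4826 ± 1150 CPM in XZ153 and 1271 ± 156 in ZD9, a log2 fold change of 1.92 with an SE of 0.75 that did not pass (adjusted p = 0.286).

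The profile bdi-MIR7757-p3_1ss12AG, at 3H 667604204 to 667604224, had 446 ± 438 CPM in XZ153 and was listed at 0 in ZD9 (adjusted p = 0.0155 by edgeR). The profile osa-miR398b_1ss20TC, at 3H 637805891 to 637806005, was at 0 in XZ153 and had 3675 ± 3584 CPM in ZD9 (adjusted p = 0.0155 by edgeR). Without any 1 ZD9 control library bdi-MIR7757-p3_1ss12AG did not pass (adjusted p = 0.0963, 0.104 and 0.0850 by edgeR). Without any 1 XZ153 control library osa-miR398b_1ss20TC did not pass (0.171, 0.0941 and 0.153), nor without ZD9 control 2 days replicate 2 (0.0569). Among those that did not pass, hvu-MIR397a-p5 at 6H 95336398 to 95336510 had 271 ± 195 CPM in XZ153 and 52631 ± 68370 in ZD9, a log2 fold change of -7.60 with an SE of 1.99 (adjusted p = 0.0725 by edgeR). This mean is above that of its family because profiles and families were scaled by separate TMM factors, 0.454 and 1.19 in ZD9 control 2 days replicate 2, so CPM of the 2 levels cannot be set side by side. The 6 libraries with under 10% of the variable families had profile factors of 0.454 to 0.860 and family factors of 1.19 to 2.15. The scaling thus raised profile CPM in these libraries and lowered family CPM, and means and SDs that include them depend on it. Profiles ata-miR166b-5p_L-2R+1 and ata-MIR398g-p5_2ss9GA21TC were at 0 in XZ153 and had 203 ± 169 and 892 ± 845 CPM in ZD9. Of the copper-related list, 9 of 9 profiles were negative (p = 0.000522, adjusted p = 0.0882 by fry; camera p = 0.000932 with an estimated correlation), and 7 were lower when adjusted over the list alone. The list did not pass by camera with an estimated correlation (adjusted p = 0.157), nor by fry without the 3 variable families (adjusted p = 0.0516). It passed by fry with family sums as members (adjusted p = 0.00674), without the library with 11851 counts (0.0113), and without both that library and the variable families (0.00532). The wheat and barley and the leaf growth lists each had 1 profile lower when adjusted over the list alone. All 7 sulfate profiles were positive (adjusted p = 0.981 by fry). Replicates did not overlap for 32 of 480 profiles and 22 of 92 families, where chance gives 10% without ties and the highest other split gave 166 and 25.

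**Figure D3:**
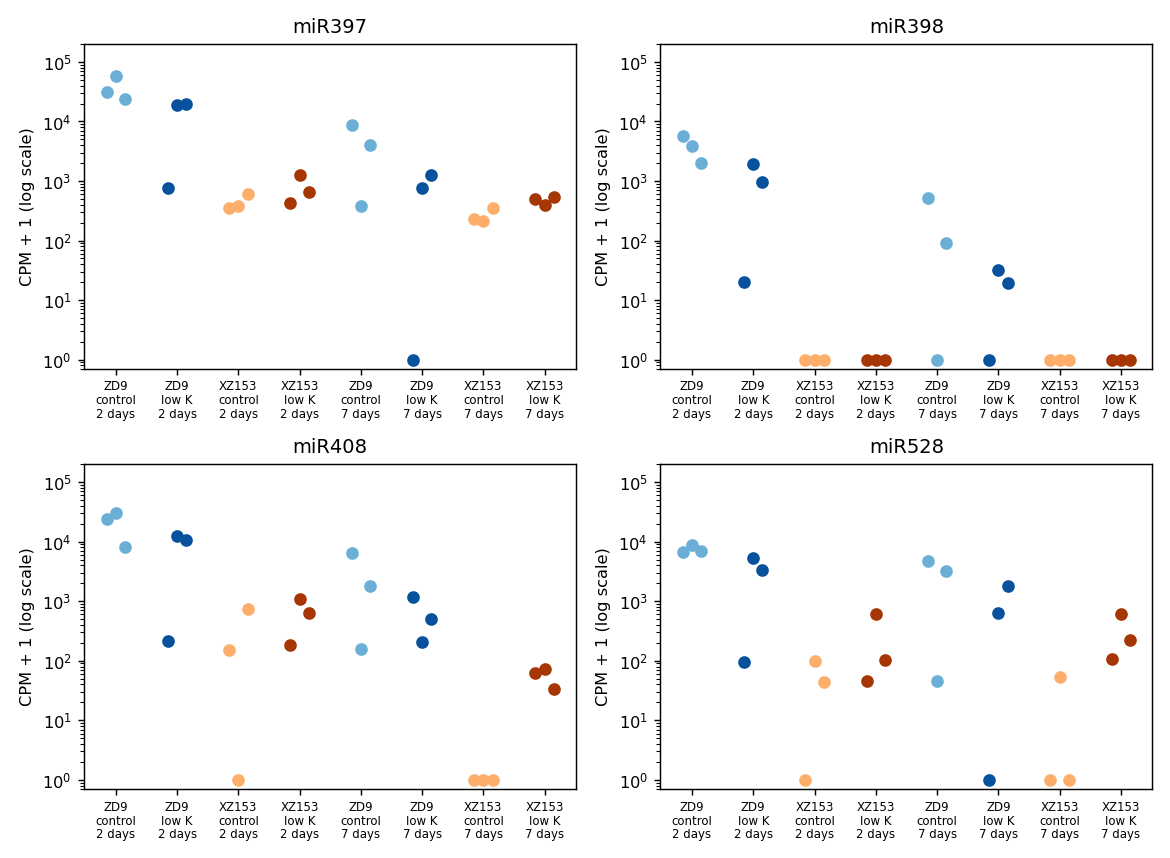
Level as CPM + 1, on a log axis, of the copper-related families miR397, miR398, miR408 and miR528, with 1 point per library by cultivar, K supply and day; points at 1 are libraries listed at 0. At 2 days under control K, miR397 had means of 447 in XZ153 and 37707 in ZD9.

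At 7 days under control K, the copper-related miR408, which targets plantacyanin and laccase messengers, was lower in XZ153. Families miR397, miR398 and miR528 were lower by their means and did not pass by edgeR. The cereal family miR5051 kept a higher mean in XZ153, and the sulfate family miR395 was higher by its mean.

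By edgeR, 0 of 480 profiles passed, with 32 at an unadjusted p under 0.05, and 1 of 92 families passed, lower in XZ153; DESeq2 called 15 profiles and 6 families. Family miR408 was listed at 0 in XZ153 and had 2776 ± 3195 CPM in ZD9 (adjusted p = 0.0135 by edgeR). It did not pass without any 1 of the 3 XZ153 control libraries (adjusted p = 0.0681, 0.0501 and 0.0937 by edgeR). Family miR397 had 262 ± 75.5 and 4428 ± 4226 CPM, a log2 fold change of -4.07 with an SE of 1.17, and miR528 had 17.8 ± 30.8 and 2709 ± 2430 CPM, -7.33 with an SE of 2.15, each with an adjusted p of 0.0854 by edgeR. Family miR398 was at 0 against 202 ± 277 CPM (adjusted p = 0.132 by edgeR). Family miR5051 had 3500 ± 760 and 831 ± 152 CPM, a log2 fold change of 2.07 with an SE of 0.75, and miR395 had 2091 ± 615 and 445 ± 170 CPM, 2.23 with an SE of 1.07. None of the 5 profiles with the smallest p passed. Profiles osa-miR408-3p_L-1 and hvu-miR156a_2ss9GT21AT were at 0 in XZ153 and had 2632 ± 2953 and 118 ± 95.8 CPM in ZD9, and osa-miR528-5p had 12.2 ± 21.1 and 2499 ± 2194 CPM. In turn bdi-MIR7757-p3_1ss12AG had 176 ± 78.5 CPM in XZ153 and ata-miR169i-5p_R+1 77.6 ± 68.4, both at 0 in ZD9. The copper-related list had an adjusted p of 0.981 by fry, with 6 profiles lower when adjusted over the list alone, and the phase change list had 1 lower. Replicates did not overlap for 44 of 480 profiles and 9 of 92 families, where chance gives 10% without ties.

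Whether the genotypes answer low K in different ways is asked by the difference of their responses. At 2 days none passed by edgeR, and the leaf growth family miR319 and auxin-related miR390 had the smallest p. At 7 days the copper-related miR408, the growth regulator miR396 in its 3' arm and miR390 led, and none passed by edgeR.

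For 2 days, edgeR called 0 profiles and 0 families, with 12 profiles and 1 family at an unadjusted p under 0.05; DESeq2 called 1 profile and 0 families. Family miR319 had a log2 difference of -3.31 with an SE of 1.44 (adjusted p = 1.00 by edgeR), and was nearest to 0 without XZ153 control 2 days replicate 2. The named profiles ata-miR390-3p, gma-MIR6300-p3_10 and ata-miR166a-5p were above 0 in 3, 2 and 3 of 12 libraries, and bdi-MIR169b-p5 and gma-MIR5368-p3_2ss17AC19AG in 9 and 5. For 7 days, edgeR called 0 profiles and 0 families, with 30 profiles and 10 families at an unadjusted p under 0.05; DESeq2 called 9 profiles and 2 families. Profiles ata-miR396c-3p, osa-miR408-3p_L-1, ata-miR390-3p, PC-3p-108036_150 and gma-miR6300_L-1R+8 were above 0 in 3, 8, 5, 2 and 7 of 12 libraries (adjusted p from 0.598 to 0.625 by edgeR). Among XZ153 libraries at 7 days, ata-miR396c-3p and ata-miR390-3p were above 0 only in control replicate 3, with 762 and 477 counts. In that library the variable families held 0.344% of the counts. The copper-related list had 1 profile higher when adjusted over the list alone. The median SE of these differences was 2.35 at 2 days and 2.38 at 7 days.

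Age under control K was the next comparison, as shoots at 7 days are older than at 2 days. In ZD9 the copper-related miR397 and miR398 were lower at 7 days by their means, and a miR169 isoform seen at 2 days was at 0. In XZ153 the growth regulator miR396 and miR408 were lower by their means. None of these passed by edgeR.

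In ZD9, edgeR called 0 profiles and 0 families, with 19 profiles and 5 families at an unadjusted p under 0.05; DESeq2 called 5 profiles and 1 family. Family miR397 had 4428 ± 4226 CPM at 7 days and 37707 ± 18660 at 2 days, a log2 fold change of -3.09 with an SE of 1.12 (adjusted p = 0.649 by edgeR), and miR398 had 202 ± 277 and 3878 ± 1872 CPM, -4.26 with an SE of 1.80. The profile ata-miR169i-5p_R+1 was above 0 in 3 of 3 libraries at 2 days and at 0 at 7 days (adjusted p = 0.368 by edgeR), as were PC-3p-108305_148 and lus-miR159b_R+1. The profile lja-MIR7544-p5_2ss5AT19AC was above 0 in 2 libraries at 7 days alone, and osa-MIR5339-p3_1ss3GA had a log2 fold change of -4.03 with an SE of 1.51. The nitrogen-related list had 1 profile lower when adjusted over the list alone. Replicates did not overlap for 44 of 480 profiles and 32 of 92 families, where chance gives 10% without ties and the highest other split gave 165 and 16.

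In XZ153, edgeR called 0 profiles and 0 families, with 13 profiles and 2 families at an unadjusted p under 0.05; DESeq2 called 4 profiles and 1 family. Family miR396 had a log2 fold change of -1.02 with an SE of 0.43, and miR408 was at 0 at 7 days against 294 ± 388 CPM at 2 days (adjusted p = 0.145 by edgeR). Profiles osa-miR408-3p_L-1 and hvu-miR156a_2ss9GT21AT were above 0 in 2 libraries at 2 days and at 0 at 7 days. In turn, gma-miR6300_L-1R+2, ata-miR166b-5p_L-2R+1 and ath-miR8175_L-2_1ss17GA were above 0 in 3, 2 and 3 libraries at 7 days and at 0 at 2 days. The copper-related list had 1 profile lower when adjusted over the list alone. Groups were apart without overlap for 13 of 480 profiles and 6 of 92 families, where chance gives 10% without ties.

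The low K response could also differ between days within a genotype. In ZD9 a predicted candidate led, and in XZ153 miR6300 and a miR172 isoform, part of the pathway that promotes the adult phase, were among those with the smallest p. None passed by edgeR.

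In ZD9, edgeR called 0 profiles and 0 families for this difference, with 4 profiles and 3 families at an unadjusted p under 0.05; DESeq2 called 2 profiles and 0 families. Profiles PC-3p-139466_63, gma-MIR6300-p3_10, lus-miR159b_R+1, ata-miR169i-5p_R+1 and gma-miR6300_L-1R+8 were above 0 in 4, 3, 6, 7 and 5 of 12 libraries (adjusted p from 0.883 to 1.00 by edgeR). In XZ153, edgeR called 0 profiles and 0 families, with 27 profiles and 3 families at an unadjusted p under 0.05; DESeq2 called 10 profiles and 2 families. Family miR6300 had a log2 difference of 2.07 with an SE of 0.85. Profiles mtr-MIR2592aw-p5_2ss7TG17GT, ptc-MIR156h-p5_2ss2AG17CA, gma-MIR5368-p5_2ss9GT18TC, osa-miR5072_L-4_1ss13GT and bdi-miR172a-3p_1ss9GT were above 0 in 7, 3, 6, 7 and 7 of 12 libraries (adjusted p = 0.416 by edgeR). Of these, gma-MIR5368-p5_2ss9GT18TC belongs to the variable families. The profile mtr-MIR2592aw-p5_2ss7TG17GT does not, but was also low where their share was lowest. It had 11 counts in XZ153 low K 2 days replicate 3 and 0 in XZ153 control 7 days replicate 3.

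Plant miRNAs are mostly of 21 nt, cut by DCL1, while 24 nt sequences belong to other pathways. Filtered counts were grouped by the listed length of each profile, so the shares that follow are not those of all reads in a library. Profiles of 21 nt made up 23.5% to 75.0% of these counts, those of 20 nt or less 11.2% to 48.0%, and those of 22 nt up to 19.5%. In XZ153 control at 7 days, 21 nt held 75.0% in replicate 3 and 30.3% in replicate 1. The variable families held 0.344% and 67.1% there. Sequences of 23 nt held 0.595% to 11.5% and those of 24 nt or more 0.173% to 2.95%. The 22 nt share, the length that can start phased small RNAs, was higher by 1.78 percentage points under low K (two-sided permutation test, p = 0.0222, adjusted p = 0.111 over 5 classes), which did not pass. For 20 nt or less the difference was -3.03 points (permutation p = 0.546) and for 21 nt 1.23 points (permutation p = 0.850). Within XZ153 the 22 nt difference was 2.29 points at 2 days (exact permutation p = 0.1, the smallest that 3 against 3 allows) and 4.18 at 7 days (exact permutation p = 0.2). In ZD9 it was -0.363 and 1.02, and the difference between the genotypes was within chance on both days (exact permutation p = 0.145 and 0.28).

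The low K responses of the 2 genotypes were also compared across all 480 profiles, which are not independent replicates. Between ZD9 and XZ153 the Pearson correlation was 0.154 at 2 days (Spearman 0.185, exact p = 0.67 for each over 400 reassignments of K labels) and 0.161 at 7 days (Spearman 0.151, exact p = 0.44 for each). Between days it was -0.267 in ZD9 (exact p = 0.24; Spearman -0.304, exact p = 0.18) and 0.0779 in XZ153 (exact p = 0.93; Spearman 0.0388, exact p = 0.96). Adjusted over the 4 relations, the smallest p was 0.88 for Pearson and 0.72 for Spearman, so a shared response was not detectable with these libraries.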

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

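Fits without miR5368, miR6173 and miR4995, with their log2 share as a covariate, without the library with 11851 counts (ZD9 low K 7 days replicate 1), or without both the families and that library were chosen after seeing the data, as was leaving out libraries for family sums. Over 36 counts and comparisons, 443 of 532 alternative values kept their direction and size within 1.5 times, 78 moved and 11 reversed. Most edgeR counts of calls were 0, and a count that stayed at 0 was taken as kept. The number kept is therefore no measure of how firm the results are. Over 119 values of named profiles and families, 2119 of 2312 alternative values kept direction and side of the threshold, 22 no longer passed, 110 passed newly and 61 reversed. Another 14 values, of 13 profiles or families, could not be given because every library left was at 0. The cause was not tested for any value that follows, except where a setting removes samples.

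DESeq2 called more profiles than edgeR in every comparison. It called 1 for low K in ZD9 at 2 days, 1 in XZ153 at 2 days, 1 in ZD9 at 7 days, 10 in XZ153 at 7 days and 8 for the mean low K response, against 0 by edgeR in each. For XZ153 against ZD9 it called 13 at 2 days (2 by edgeR) and 15 at 7 days (0 by edgeR). For the difference of responses between cultivars it called 1 at 2 days and 9 at 7 days, for age 5 in ZD9 and 4 in XZ153, and for the difference between days 2 in ZD9 and 10 in XZ153, against 0 by edgeR. Among families it called 1 for low K in ZD9 and 6 in XZ153 at 7 days, 2 for the mean response, 6 for XZ153 against ZD9 at 2 days (3 by edgeR) and 6 at 7 days (1 by edgeR). It also called 2 families for the cultivar difference at 7 days, 1 for age in ZD9, 1 for age in XZ153 and 2 for the day difference in XZ153. For miR160 in the mean response it gave 0.0408 in place of -0.02.

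With no filter on low counts, edgeR called 6 profiles for low K in ZD9 and 9 in XZ153 at 7 days, 8 and 2 for XZ153 against ZD9 at 2 and 7 days, 1 and 3 for the cultivar difference at 2 and 7 days, and 1 each for the day difference in ZD9 and XZ153. Families numbered 5 and 4 for XZ153 against ZD9 at 2 and 7 days and 1 for age in XZ153. In the mean response miR160 became 0.0547, miR164 0.00964 and miR393 0.00482. RLE factors gave 1 profile for XZ153 against ZD9 at 7 days and 0.0368 for miR160. A mean CPM of at least 10 left 1 profile for XZ153 against ZD9 at 2 days, and limma on the authors' normalized values called 10 at 2 days and 2 at 7 days. A fit to the compared libraries alone called 0 profiles for XZ153 against ZD9 at 2 days and 2 for the cultivar difference at 7 days. Family sums as list members gave 1 passing list, the copper-related families in XZ153 against ZD9 at 2 days.

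Without the 3 variable families, edgeR called 4 profiles and 5 families for XZ153 against ZD9 at 2 days and 2 profiles at 7 days, and the correlation of low K responses between cultivars at 2 days was -0.126 in place of 0.154. With their share as a covariate it called 6 profiles and 5 families at 2 days and 7 profiles and 3 families at 7 days. It also called 1 profile each for low K in ZD9 at 2 days and XZ153 at 7 days, the cultivar difference at 2 days, age in ZD9, and the day difference in ZD9 and in XZ153, and gave 0.0607 for miR319 in the mean response. Without both the families and the library with 11851 counts it called 5 profiles and 6 families at 2 days, 7 profiles and 4 families at 7 days, and 1 list. The mean responses of miR160, miR164, miR393 and miR444 were then 0.115, 0.0850, 0.0601 and 0.0143. Profiles outside the 3 families that were also low where their share was lowest, such as mtr-MIR2592aw-p5_2ss7TG17GT, stayed in these fits.

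Replicate numbers do not pair the libraries. Deviations from group means correlated at a mean of -0.0339 over 84 pairs of libraries with the same number, 30 of them over 0.1, and 0.0304 over 168 pairs with different numbers, and 7 of 24 libraries correlated best with their own number. With the number as a block, 2 families passed for XZ153 against ZD9 at 7 days in place of 1, and no other count of calls moved by over 1.5 times.

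Leaving out 1 library at a time changed each call between cultivars. For XZ153 against ZD9 at 2 days, called profiles ranged from 0 (without ZD9 control 2 days replicate 2) to 4 (without the library with 11851 counts), and 1 was called without any other of the 6 libraries compared. Called families ranged from 0 (without XZ153 control 2 days replicate 2) to 5 (without the library with 11851 counts), with 1 without ZD9 control 2 days replicate 1 or XZ153 control 2 days replicate 1. At 7 days profiles ranged from 0 to 1 (without ZD9 control 7 days replicate 2), and families from 0 (without any 1 of the 3 XZ153 control libraries) to 4 (without ZD9 control 7 days replicate 2 or the library with 11851 counts). For age in XZ153 families ranged from 0 to 1 (without XZ153 control 2 days replicate 2). Without the library with 11851 counts 1 list passed.

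Over 14 alternatives for family sums at 2 days, adjusted p ranged from 1.19e-08 to 0.0811 for miR397 and from 2.34e-05 to 0.0811 for miR398. It ranged from 9.41e-05 to 0.632 for miR319 at 2 days and from 1.60e-07 to 0.0937 for miR408 at 7 days. A mean CPM of at least 10, the compared libraries alone and limma on the authors' normalized values were tried on profiles only. Family miR397 did not pass without XZ153 control 2 days replicate 1 (0.0649) or 2 (0.0811). Family miR398 did not pass without either of these (0.0649 and 0.0811) or ZD9 control 2 days replicate 1 (0.0553). Family miR319 did not pass without XZ153 control 2 days replicate 2 (0.632) or any 1 ZD9 control 2 days library (0.149, 0.109 and 0.109). Family miR408 did not pass without any 1 XZ153 control 7 days library (0.0681, 0.0501 and 0.0937). For bdi-MIR7757-p3_1ss12AG the range was 2.66e-07 to 0.140, with 4 of 17 alternatives not passing, and for osa-miR398b_1ss20TC 7.45e-05 to 0.195, with 6 of 17 not passing.

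With single libraries left out, the log2 change of gma-MIR5368-p5_1ss9AG in ZD9 at 7 days ranged from -0.87 (without the library with 11851 counts) to 5.54. For ata-miR166a-5p in the cultivar difference at 2 days the range was -15.51 to 1.43 (without XZ153 control 2 days replicate 2), and for ata-miR169i-5p_R+1 in the day difference in ZD9 it was -0.00544 (without ZD9 low K 7 days replicate 3) to 6.51. Mean low K responses ranged from -0.32 to 0.0249 for miR156, -0.22 to 0.20 for miR160, -0.21 to 0.19 for miR164, -0.36 to 0.0371 for miR172, -0.81 to 0.10 for miR319, -0.26 to 0.14 for miR393 and -0.22 to 0.11 for miR444. The upper ends came without the library with 11851 counts, except for miR172 (ZD9 control 7 days replicate 2) and miR319 (XZ153 control 2 days replicate 2).

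With a replicate number left out, the low K difference ranged from -1.25 to 4.82 points for 21 nt, from -0.563 to 1.08 for 23 nt and from -0.473 to 0.0914 for 24 nt or more. The correlation of responses ranged from -0.140 to 0.263 between cultivars at 7 days, from -0.599 to 0.249 between days in ZD9 and from -0.697 to 0.380 between days in XZ153. Depth and spread limit these data: the biological coefficient of variation was 1.28 for profiles and 1.08 for families, and 1 library held 11851 counts. Other libraries also stood apart from their replicates in the correlation across profiles.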

Other observations

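Tests on all 24 libraries by cultivar, of relations between copper-related families, and of the covariate, of strain variants in copper-related families and miR9674, of low K supply and of short fragments were chosen after the results were seen. The cereal family miR5051 was the clearest difference between the genotypes once K supply and day were pooled. It had 4483 ± 1112 CPM in XZ153 and 928 ± 431 in ZD9 (SD, n = 12 each), a log2 difference of 3.01 (permutation of cultivar labels within K supply and day, two-sided, p = 1e-05, the smallest the resamples can give, adjusted p = 0.00092), with no overlap in 4 of 4 conditions, where chance gives 10% each without ties. Without the library with 11851 counts the difference was 2.20 (adjusted p = 0.00322). Family miR408 was lower in XZ153, at 246 ± 366 against 7967 ± 10047 CPM (adjusted p = 0.00322), and miR398 was listed at 0 in 12 XZ153 libraries against 1267 ± 1854 CPM (adjusted p = 0.00705). Of 92 families 3 passed this permutation test, 17 had an unadjusted p under 0.05, and 10 passed without that library. These 10 include the copper-related miR397, miR398 and miR408 (adjusted p = 0.00322 each) and miR528 (0.00607) by the permutation test, where miR397 and miR528 did not pass with it (0.182 and 0.109).

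The copper-related families moved together within ZD9. Across 11 ZD9 libraries, without the one with 11851 counts, Pearson r between pairs of miR397, miR398, miR408 and miR528 ranged from 0.879 to 0.991 and Spearman rho from 0.918 to 0.964 (permutation tests over 10 relations, largest adjusted p 0.000114 and 0.000243). Leaving out the 2 farthest libraries, the lowest r was 0.840. Deviations from group means gave r from 0.939 to 0.988, without a check that left libraries out. In ZD9 low K 2 days replicate 1 the leading profiles of miR397, miR398, miR408 and miR528 had 109, 5, 43 and 24 counts. Replicate 2 had 2430, 184, 1698 and 710. In ZD9 control 7 days replicate 2 they had 37, 0, 24 and 9, against 1025, 43, 838 and 608 in replicate 1. The relation within groups thus rests in part on these libraries. The mean of the copper-related families with the share of the variable families had r -0.159 (permutation p = 0.71) and rho 0.209 (p = 0.537), but 0.543 and 0.633 without the 2 farthest libraries, so a part of library composition stays open. In other plants the SPL7 transcription factor raises miR397, miR398 and miR408 when copper is short.

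The copper-related families miR397 and miR398 at 2 days and miR408 at 7 days were lower in XZ153 than in ZD9 under control K, and miR528 had lower means on both days without passing. A few families taking most of the counts is argued against, as the median log2 fold change at 2 days with their share as a covariate was -6.96, a median that includes the fitted value of miR398, listed at 0 in XZ153. A strain variant against the reference stays open. For miR397, miR408 and miR528 the most abundant profile of each was above 0 in at least 8 of 12 XZ153 libraries. An entry pools the reads of all isoforms at 1 end of a precursor, so this does not show that the exact sequence was read. XZ153 totals of these profiles were 540, 486 and 326 counts, against 47261, 28242 and 10309 in ZD9. Of the ZD9 totals, 31584, 18308 and 4960 counts came from ZD9 control 2 days replicate 2, the library with the most counts. A variant in some or all of the copies cannot be excluded. For miR398, 0 XZ153 libraries listed the profile or another of the family. The cultivar as such may explain the difference, but in the 12 low K libraries, which entered the calls only through the filter, the scaling and the shared spread, the mean log2 difference was -2.51 (exact permutation p = 0.135), with -4.32 at 2 days (p = 0.2) and -0.69 at 7 days (p = 0.9). Without the library with 11851 counts, in a test added after this result was seen, it was -3.45 (exact permutation p = 0.01 over 200 assignments), with -2.59 at 7 days (p = 0.1, the smallest that 10 assignments can give), so the answer turns on 1 library and stays open, with copper status not tested.

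The share of miR5368, miR6173 and miR4995 differed strongly between replicates. Low K supply as the cause is argued against, because 3 of 4 control groups differed by over 5-fold between replicates. Library depth is argued against as well, with a Spearman rho of 0.0609 with the total count (permutation p = 0.777). More short fragments of every kind is a candidate explanation: the share of 20 nt or less among the other counts rose with it (Spearman rho 0.677, permutation p = 0.00037, adjusted p = 0.000463; Pearson r 0.545, and 0.503 without the 2 farthest libraries). Longer classes were not tested among the other counts, so a rise limited to short sequences was not shown. Over all counts, longer classes also went with the share. In ZD9 control 2 days replicates 1 to 3 it was 59.3%, 0.721% and 60.2%. There 23 nt held 7.41%, 0.793% and 9.55%, and 24 nt or more 2.05%, 0.173% and 2.77%. The total of the authors' normalized values also followed the share of the 3 families (Pearson r 0.879, Spearman rho 0.937, permutation p = 1e-05, the smallest the resamples can give; r 0.863 without the 2 farthest), and no biological explanation other than low K supply was tested.

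Some profiles were listed in 1 cultivar alone: 15 were above 0 in at least 6 libraries of a cultivar and at 0 in all 12 of the other, 5 in XZ153 and 10 in ZD9, 4 of them copper-related. Uneven detection that does not follow cultivar is argued against. Reassigning cultivar labels within K supply and day gave a median of 0 and a highest of 17 such profiles. As many were given by 7 of 100000 reassignments (permutation p = 8e-05). Detection that itself differs between cultivars stays open, as this test cannot address it. ZD9 libraries reached up to 531215 counts and 551 profiles above 0, and XZ153 libraries up to 212902 and 445. A strain variant against the reference may explain the miR9674 pair, but different loci stay open too, since the table places the pair on 3H and 2H. In this pair 2 profiles of that family differ by G9A, counted from the 5′ end: ata-miR9674c-3p_L-1R+1_1ss18CT in 10 ZD9 libraries and ata-MIR9674c-p5_2ss9GA17CT in 7 XZ153 libraries. For the others it stays open, since 0 of 13 had such a partner.

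The profile bdi-MIR7757-p3_1ss12AG was in 12 of 12 XZ153 libraries, with 18 to 109 counts, and in 0 of 12 ZD9 libraries.

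Calls were also counted over other splits of the same libraries. With 3 against 3 there are 10 splits, too few for a share under 0.05. XZ153 against ZD9 at 2 days called 2 profiles and 3 families, reached by 1 of 10 splits each, with 0 as the highest other. At 7 days it called 1 family, reached by 1 of 10, with 0 as the highest other, and 0 profiles, with 0 as the highest other. The 4 single low K comparisons and age in ZD9 called 0 profiles and 0 families, with 0 as the highest other. A count of 0 is reached by all 10 splits whatever the data, so these say nothing about chance. For age in XZ153 the real split called 0 and another split 14 profiles and 4 families, which points to a structure of the samples.

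Where 100 splits were drawn, each real count was 0, which all 100 reach whatever the data, so this count says nothing about chance. The highest other split called 29 profiles for the mean low K response, 12 and 1 for the cultivar difference at 2 and 7 days, and 1 and 192 for the day difference in ZD9 and XZ153, with 0 families in each. Splits with 29 or 192 calls point to a structure of the samples.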
